A study of Homo sapiens with 28 samples.

How the data were processed

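Jurkat cells, a human T cell leukaemia line, were grown in RPMI1640 and activated with phorbol myristate acetate (PMA, 0.5 µg/ml), which switches on protein kinase C, and the lectin phytohaemagglutinin (PHA, 2 µg/ml), which engages the T cell receptor, per the labels. RNA was collected before activation and 1, 2, 3 and 4 h after it. RNA was also labelled with 4-thiouridine, a uridine analogue taken up into newly made RNA. Per the labels' protocols, the labelled part was coupled to biotin-HPDP and pulled down on streptavidin beads after Trizol extraction, and libraries were made with ScriptSeq after Ribo-Zero depletion of ribosomal RNA. The length of the labelling is not given in the sources used here. The 28 samples form 10 groups, with 14 total RNA and 14 labelled RNA samples. Each group had 3 samples, described per the labels as biological replicates, except total and labelled RNA at 1 h with 2 each.

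The authors aligned reads with TopHat2, counted them with HTSeq and used edgeR, on the hg19 build, per the submitters' processing notes, which give no versions. The deposited table holds 7485 genes and 7484 distinct symbols, since CRYBG3 fills 2 entries. For every group the deposited table gives the authors' mean and SD of a normalised expression signal, per the file headers, and no value for a single sample. These deposited means sum to between 913919 and 1037463 per group, near what a per-million scale would give. How the labelled values were normalised against the total values is not given in the sources used here, so a labelled-to-total ratio shows which genes lay above or below the typical gene and not an absolute share of new RNA. A separate deposited column in RPKM, the authors' length-scaled read density, correlated with the logarithm of the mean total value at 0.898 across genes (Pearson, on logarithms), and was used for this check alone. Decay rates in the authors' deposited table are on a natural log scale. Each deposited rate was recovered as the natural log of total RNA at an hour, less 0.266 times labelled RNA at that hour, divided by total RNA of the hour before. For unactivated cells the same total value stood above and below the line. The rates are therefore built from the same means as the other comparisons, and have no value where the scaled labelled part reached the total, which held for 155 genes before activation and 138, 134, 91 and 113 genes at 1, 2, 3 and 4 h. The deposited T score of each rate change matched a pooled-variance formula on the deposited means and SDs, within a relative tolerance of 0.001, for all of the 7252, 7252, 7283 and 7264 genes that had one at 1, 2, 3 and 4 h. The authors' deposited table also holds LOD scores of HuR binding at 0 h and 4 h and in 293 cells, and 3 yes-or-no calls of HuR targets, whose making is not given in the sources used here.

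Depth is unknown for most samples because no counts were used here. The total RNA means and SDs at 1 h, which come from 2 samples, gave back both values of each gene. For 3047 of 3047 genes with values under 50 both were whole multiples of a step, within a tolerance of 0.02 of a read, which puts these libraries at 1.12e+07 and 1.11e+07 reads if the values are per-million values. In labelled RNA at 1 h this held for 9 of 2699 genes (0.333%), so single reads could not be recovered there. A count test would need more than the 1 group and was not run. The median coefficient of variation between samples ran from 6.37% to 11.2% in total RNA and from 10.4% to 18.2% in labelled RNA, with the highest value in labelled RNA of unactivated cells.

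The design had been fixed for values of single samples. Because the table gives means and SDs, limma 3.58.1 in R 4.3.3 was run from these summaries: the mean on the log2(value + 1) scale, and its SD carried to that scale to first order. Residual variances were pooled over the 5 groups of one kind of RNA (9 degrees of freedom) or over all 10 groups (18 degrees of freedom), and moderated with a mean-dependent trend and the robust option. Total and labelled values of one culture were treated as independent, since the means cannot show their covariance. P-values were adjusted over genes by Benjamini-Hochberg with a threshold of 0.05, and all changes are log2 changes ± SE on the log2(value + 1) scale, which understates the change of low genes. The low-value filter removed no gene. The lowest mean of a gene ran from 1.08 to 2.45 over the groups, so genes without signal at some hour are not among those counted here. Tests compared each hour with unactivated cells and 4 h with 1 h, in total and in labelled RNA. Labelled was compared with total RNA at each time, and the change of that ratio from unactivated cells was tested as an interaction. Samples, comparisons, gene lists and the other settings to try were fixed before the data were examined, except for those named below as chosen later.

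Of 33 gene lists, 27 had at least 5 measured members and were tested with cameraPR in limma at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. An estimated correlation needs single samples and could not be had from means and SDs, so camera on ranks was run in its place. Where members of a list vary together more strongly than the preset 0.01, the list p-values are too small. Lists with fewer measured members were not tested: activation markers and cytokines (2), mitochondrially encoded mRNAs (0), and markers of B cells (0), myeloid cells (2), fibroblasts and epithelium (2) and erythroid cells (0). HuR target calls were tested in the same way, as lists chosen by the authors.

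Named genes followed a fixed rule. It took 14 genes whatever their values, of which 6 were present (JUNB, MYC, NFKBIA, ELAVL1, GAPDH and ACTB); EGR1, FOS, CD69, IL2, TNF, IL8, NR4A1 and ZFP36 were not analysed here. It took the 5 largest rises and 5 largest falls at 1 h and 4 h in total RNA, labelled RNA and their ratio, and the 8 highest and 8 lowest labelled-to-total ratios in unactivated cells, among genes past the threshold with a mean of at least 5. The rule's condition that samples do not overlap was replaced by ranges of mean ± SD that do not overlap. It also took the 4 members of each list with the smallest p. Some genes that the rule took are not reported here. Ensembl identifiers matched the reference gene names for 7396 genes, and 6876 carry their current symbol. Transcript features came from GENCODE 29, which is not the authors' build, so no coordinates are printed.

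Of the settings fixed beforehand, those that could be run were quantile normalisation, median centring, a stricter filter (lowest group mean of at least 5), pseudocounts of 0.1 and 5, only the groups compared, and a fold threshold of 1 on the log2 scale. Settings chosen after seeing the data were the linear scale, values rebuilt from mean and SD, a constant prior variance and ranks for lists, as well as all tests on HuR calls and decay rates. For gene lists, quantile normalisation, the stricter filter and the pseudocounts were also chosen later, and only median centring had been fixed beforehand. The limma step was tested on simulated data of 7485 genes made from the deposited means and SDs. It found 66% of 50 genes changed by 0.5 on the log2 scale and 100% of 50 changed by 1 in total RNA at 4 h, 58% and 96% in total RNA at 1 h, 24% and 80% in labelled RNA at 4 h, 12% and 58% in labelled RNA at 1 h, 24% and 78% for the ratio change at 4 h, and 6% and 60% for the ratio change at 1 h. With no gene changed it called 0 genes in each of these by limma, while between 5.02% and 5.70% of genes had an unadjusted p under 0.05. Beside 200 changed genes it also called 9, 3, 9, 11, 12 and 9 unchanged genes in the same order of comparisons, or 4.74%, 1.71%, 5.77%, 8.09%, 8.16% and 7.44% of all its calls. Each simulated gene had 1 coefficient of variation over all hours of a kind of RNA. In the data its median was 18.2% in labelled RNA of unactivated cells, against 10.4% to 12.4% at the later hours. False calls from such unequal spread could not show in the simulation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.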

Results

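Gene expression was followed in Jurkat T cells over the first 4 h after activation with PMA and PHA. Total RNA and newly made, 4-thiouridine-labelled RNA were sequenced from unactivated cells and at 1, 2, 3 and 4 h. Each group had 3 samples, except both kinds of RNA at 1 h with 2. All group values below are the authors' means with the deposited SD, on their per-million-like scale, for 7485 genes. GAPDH, a glycolytic enzyme often taken as a reference, had a mean total value of 1687 ± 114 before activation and 1649 ± 219 at 4 h. ELAVL1, which encodes the RNA-binding protein HuR, had 131 ± 6.57 and 124 ± 5.28. Neither was called at any hour in total or labelled RNA by limma, with adjusted p between 0.0938 and 0.986 for ELAVL1. Of marker genes of other cell types, the table held AIF1 and VCAN of myeloid cells and VIM and THY1 of fibroblasts.

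Activation was first read in total RNA, which holds new and old transcripts together. After 1 h, IER3, an early response gene that protects from apoptosis, rose from 4.59 ± 0.504 to 143 ± 29.4, a log2 change of 4.69 ± 0.12. DUSP2, a phosphatase that switches off MAP kinases, rose from 19.2 ± 2.90 to 521 ± 81.3 (4.69 ± 0.12). JUNB, a subunit of the AP-1 transcription factor, rose by 3.03 ± 0.14, KLF10, a TGF-beta-inducible transcription factor, by 3.68 ± 0.21, and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, by 2.88 ± 0.14. The largest falls were in ARRDC3, an arrestin family member (-1.39 ± 0.14, from 26.6 ± 2.44 to 9.53 ± 0.559), and the transcription factor SOX11 (-1.30 ± 0.16). They were followed by LRIG3 (-1.08 ± 0.18), HILPDA, a lipid droplet protein (-1.04 ± 0.20), and C22orf29 (-0.79 ± 0.14). MYC, the growth-driving transcription factor, was not called at 1 h (-0.03 ± 0.12, adjusted p = 0.97 by limma), nor was the actin gene ACTB (0.26 ± 0.13, adjusted p = 0.63 by limma).

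Of 11 immediate early genes, transcription factors and regulators induced without new protein, 7 rose, 0 fell and 4 were not called at 1 h, with 8 rising when adjusted over the list alone. These 11 are the measured part of a list of 30, and of 39 activation markers and cytokines only 2 were measured. The shares therefore leave out much of the known response. MAP kinase phosphatases and Sprouty feedback inhibitors had 3 of 7 rise, 0 fall and 4 not called (5 up adjusted over the list alone). DUSP5 stood at 2.70 ± 0.15 and SPRY2 at 1.08 ± 0.14. Targets and feedback inhibitors of NF-kB had 6 of 17 rise, 0 fall and 11 not called (7 up adjusted over the list alone). They included TNFAIP3, the deubiquitinase A20 that shuts the pathway off (2.83 ± 0.14), CD83, a surface marker of activated lymphocytes (2.08 ± 0.11), and BIRC3, an inhibitor of apoptosis (1.60 ± 0.12). Regulators of apoptosis had 2 of 21 rise, 0 fall and 19 not called (3 up adjusted over the list alone), among them MCL1, a BCL2 family survival factor (1.68 ± 0.10). In the opposite direction, 2 of 35 replication-dependent histone genes fell, 0 rose and 33 were not called. Adjusted over the list alone 17 fell, with HIST1H2AL at -0.58 ± 0.11 and HIST1H3C at -0.47 ± 0.10. The list tests in limma gave adjusted p of 4.6e-121 for immediate early genes, 5.05e-62 for the phosphatases, 1.8e-41 for NF-kB targets, 4.6e-07 for apoptosis regulators and 6.9e-22 for histones. On ranks the test of the phosphatases gave an adjusted p of 0.0546 (range over 7 alternatives 3.43e-65 to 0.0546) and that of the apoptosis regulators 0.0668 (range 1.53e-07 to 0.0668).

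Other lists passed the list test at 1 h with few or no members called. Heat shock genes, which encode protein-folding chaperones, had 1 of 14 rise (DNAJB1, 0.97 ± 0.12), 0 fall and 13 not called. There were 5 up adjusted over the list alone, and the list had an adjusted p of 0.0015 in limma. Genes of the unfolded protein and integrated stress responses had 2 of 22 rise, 0 fall and 20 not called (4 up and 1 down adjusted over the list alone). Their adjusted p was 0.0216 in limma, and 0.145 on ranks (range 0.012 to 0.145). PPP1R15A, which restores translation after stress, was at 1.45 ± 0.13. Textbook HuR target mRNAs had 2 of 23 rise, 0 fall and 21 not called (5 up adjusted over the list alone; adjusted p = 2.6e-07 in limma). KRAB zinc finger repressors had 1 of 100 rise (ZNF101, 0.59 ± 0.11), 1 fall (ZNF436, -0.55 ± 0.13) and 98 not called, the same counts when adjusted over the list alone. Their list median was -0.06 against 0.07 for other genes (adjusted p = 0.00082 in limma). Of 67 genes of ribosome biogenesis 0 were called by limma over all genes and 0 when adjusted over the list alone, with 12 up and 0 down at an unadjusted p under 0.05. Their median of 0.15 lay above other genes (adjusted p = 0.0077 in limma). Targets of p53 had 1 of 11 rise (CDKN1A, an inhibitor of cyclin-dependent kinases, 1.34 ± 0.13), 0 fall and 10 not called, with 3 up adjusted over the list alone. Their test went up (adjusted p = 0.0346 in limma) and their mean was 0.22, while their median of 0.06 lay just under that of other genes (0.07). That median turned negative with median centring (-0.02) and quantile normalisation (-0.01), but so did that of other genes (-0.02 and -0.005). The call of the p53 list ended in limma with the stricter filter (adjusted p = 0.783), with a pseudocount of 5 (0.0782) and on ranks (0.531), out of a range of 0.0256 to 0.783. Among the genes named at 1 h, KLF10, DUSP5, CDKN1A, ZNF101 and HIST1H3C lost their calls on the linear scale, with adjusted p of 0.0668, 0.882, 0.167, 0.44 and 0.203 in limma. Over their alternatives the adjusted p ran from 1.66e-145, 1.61e-40, 3.39e-08, 1.05e-05 and 0.000505 to those values. A constant prior variance also ended that of HIST1H3C (adjusted p = 0.0525 in limma).

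At 4 h the response in total RNA had widened. DUSP5, the nuclear phosphatase of ERK, rose from 3.10 ± 0.967 to 243 ± 15.6 (5.90 ± 0.14). PDGFA, a growth factor chain, rose from 1.60 ± 0.231 to 124 ± 6.83 (5.59 ± 0.12) and IER3 to 257 ± 2.35 (5.53 ± 0.11). IL27RA, the receptor of the cytokine IL-27, rose by 3.46 ± 0.17 and DUSP2 by 3.41 ± 0.11. RAG1 and RAG2, the recombinase that cuts T cell receptor genes, fell by 4.78 ± 0.10 and 2.94 ± 0.16, with RAG1 going from 349 ± 5.96 to 11.8 ± 0.545. SELPLG, the selectin ligand PSGL-1, fell by 2.48 ± 0.11, the chemokine receptor CXCR4 by 2.13 ± 0.10 (316 ± 31.4 to 71.6 ± 2.31), and ZFYVE21 by 2.11 ± 0.11. MYC fell by 1.82 ± 0.11 (adjusted p = 1.7e-10 by limma), from 242 ± 5.94 to 68.1 ± 10.9. JUNB (1.10 ± 0.13) and NFKBIA (0.98 ± 0.12) were still above unactivated cells. ACTB stood at 0.37 ± 0.12 (adjusted p = 0.017 by limma), and with quantile normalisation at 0.16 without a call (adjusted p = 0.301, range over 10 alternatives 0.000607 to 0.301). It was not called on the linear scale either (adjusted p = 0.112 by limma).

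Genes of the T cell receptor complex and its proximal signalling had 14 of 26 rise, 5 fall and 7 not called at 4 h, the same counts when adjusted over the list alone. The adaptor LCP2 (SLP-76) rose by 2.08 ± 0.14, and the adaptors SIT1 and TRAT1 by 2.04 ± 0.13 and 1.51 ± 0.10. NF-kB targets had 11 of 17 rise, 1 fall and 5 not called (13 up and 1 down adjusted over the list alone), with TNFAIP3 at 2.81 ± 0.13 and NFKB1 at 1.89 ± 0.08. The MAP kinase feedback list had 4 of 7 rise, 0 fall and 3 not called (4 up adjusted over the list alone), with SPRED1 at 2.09 ± 0.12. Immediate early genes had 7 of 11 rise, 1 fall and 3 not called (8 up and 1 down adjusted over the list alone). Apoptosis regulators had 11 of 21 rise, 4 fall and 6 not called, the same when adjusted over the list alone, with BIRC3 at 2.42 ± 0.10 and CFLAR, which blocks caspase-8, at 2.22 ± 0.14. AU-rich element binding proteins, which steer mRNA decay, had 11 of 21 rise, 1 fall and 9 not called (the same adjusted over the list alone). CELF2 rose by 1.27 ± 0.12 and RBMS1 by 1.05 ± 0.10.

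Further lists had more members fall than rise at 4 h. Mitochondrial ribosomal proteins had 14 of 58 fall, 0 rise and 44 not called (14 down adjusted over the list alone), with MRPL36 at -0.99 ± 0.16 and MRPS6 at -0.67 ± 0.10. Genes of the G2 and M phases had 16 of 50 fall, 2 rise and 32 not called (the same adjusted over the list alone). The mitotic kinase TTK fell by 0.51 ± 0.08 and the spindle checkpoint kinase BUB1 by 0.42 ± 0.08. KRAB zinc finger genes had 25 of 100 fall, 10 rise and 65 not called (the same adjusted over the list alone), with ZNF480 at -1.62 ± 0.13 and ZNF57 at -1.36 ± 0.14. Cytosolic ribosomal proteins had 4 of 73 fall, 0 rise and 69 not called (1 down adjusted over the list alone). The list tests in limma gave adjusted p of 1.8e-15 for MAP kinase feedback, 2.5e-14 for NF-kB targets, 1.5e-10 for immediate early genes, and 0.00021 for apoptosis regulators. They gave adjusted p in limma of 0.0019 for the T cell receptor list, 0.0064 for mitochondrial ribosomal proteins, 0.0252 for G2 and M genes, 0.0333 for AU-rich element binding proteins, and 0.0399 each for KRAB and cytosolic ribosomal protein genes. Median centring ended the call of KRAB and of cytosolic ribosomal protein genes (adjusted p = 0.0507 each), and quantile normalisation also that of KRAB genes (0.0784; ranges 0.0196 to 0.0784 and 0.00159 to 0.0507). Ranks ended those of MAP kinase feedback (adjusted p = 0.235, range 1.34e-16 to 0.235), apoptosis regulators (0.155, range 0.000152 to 0.155) and the T cell receptor list (0.0565, range 0.000357 to 0.0565).

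The other lists did not pass the list test in total RNA at 4 h, although single members moved. T cell identity transcription factors had 6 of 18 rise and 7 fall (7 up and 7 down adjusted over the list alone; adjusted p = 0.789 in limma), with RUNX3 at 2.25 ± 0.21 and IKZF2 at -1.05 ± 0.10. The NFAT and calcineurin pathway had 6 of 18 rise and 1 fall (7 and 2 adjusted over the list alone; adjusted p = 0.187 in limma), with the calcineurin subunit PPP3CA at 1.85 ± 0.11. Targets of p53 had 5 of 11 rise and 2 fall (the same adjusted over the list alone; adjusted p = 0.0859 in limma), with CDKN1A at 2.68 ± 0.12. Glycolysis genes had 4 of 18 rise and 3 fall (the same adjusted over the list alone; adjusted p = 0.789 in limma). Among glucose transporters, SLC2A3 stood at 2.91 ± 0.13 and SLC2A1 at -1.83 ± 0.15. Cholesterol genes had 2 of 18 rise and 6 fall (2 and 7 adjusted over the list alone; adjusted p = 0.187 in limma). The sterol carrier STARD4 rose by 1.42 ± 0.09, while the reductase DHCR7 fell by 1.39 ± 0.12 and the LDL receptor fell by 1.07 ± 0.14. Of the stress lists, the unfolded protein list had 7 of 22 rise and 1 fall, with the same counts adjusted over the list alone (adjusted p = 0.0929 in limma), led by the cystine transporter SLC7A11 at 1.95 ± 0.12. Heat shock genes had 2 of 14 rise and 3 fall (4 and 3 adjusted over the list alone; adjusted p = 0.789 in limma). For the lists that follow, the pair of counts in brackets gives members up and down adjusted over the list alone. Ribosome biogenesis had 4 of 67 rise and 14 fall (4 and 12; adjusted p = 0.143 in limma), and the respiratory chain 1 of 58 rise and 3 fall (1 and 1; adjusted p = 0.0666 in limma). S phase genes had 4 of 39 rise and 6 fall (4 and 6; adjusted p = 0.198 in limma), with the cyclin CCNE2 at 1.03 ± 0.10. Textbook HuR targets had 7 of 23 rise and 3 fall (7 and 3; adjusted p = 0.572 in limma), and histones 1 of 35 rise and 2 fall (1 and 2; adjusted p = 0.395 in limma). The mRNA decay machinery had 10 of 53 rise and 4 fall (9 and 3; adjusted p = 0.891 in limma), with the decapping enzyme DCP2 at 0.44 ± 0.08. Spliceosome genes had 3 of 43 rise and 1 fall (2 and 0), proteasome subunits 4 of 31 rise and 1 fall (3 and 0) and interferon genes 1 of 8 rise and 1 fall (1 and 1), each at an adjusted p of 0.789 in limma. Nuclear-retained RNAs had 2 of 5 rise and 0 fall (2 and 0; adjusted p = 0.816 in limma). Of the marker genes of other cell types, VIM was at 0.52 ± 0.11 (adjusted p = 0.0012 by limma), VCAN at -0.88 ± 0.16 (adjusted p = 0.00024 by limma), and AIF1 (-0.02 ± 0.11) and THY1 (0.04 ± 0.19) were not called.

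Counted over 7485 genes, limma called 70 genes in total RNA at 1 h (59 up, 11 down), 995 at 2 h (727 up, 268 down), 2229 at 3 h (1416 up, 813 down) and 2692 at 4 h (1605 up, 1087 down). With only the groups compared there were 161 calls at 1 h and 1703 at 2 h, and on the linear scale 41 at 1 h. Over the course 2775 genes changed in an F test. The direction split depended on scaling: the percent of called genes that rose was 84.3, 73.1, 63.5 and 59.6 at the 4 hours. It was 69.6, 50.2, 48.6 and 51.0 with median centring and 71.7, 52.8, 47.5 and 48.8 with quantile normalisation. Between 1 h and 4 h, 1957 genes changed (933 up, 1024 down), among them JUNB (-1.93 ± 0.14), NFKBIA (-1.91 ± 0.14) and MYC (-1.79 ± 0.12), each lower at 4 h. The split turned to 1089 up and 837 down with median centring and to 979 up and 946 down with quantile normalisation. Over this interval 10 of 35 histone genes rose, 0 fell and 25 were not called (10 up adjusted over the list alone; adjusted p = 0.0066 in limma). Meanwhile 16 of 67 ribosome biogenesis genes fell, 0 rose and 51 were not called (16 down adjusted over the list alone; adjusted p = 0.0066 in limma).

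**Figure D1:**
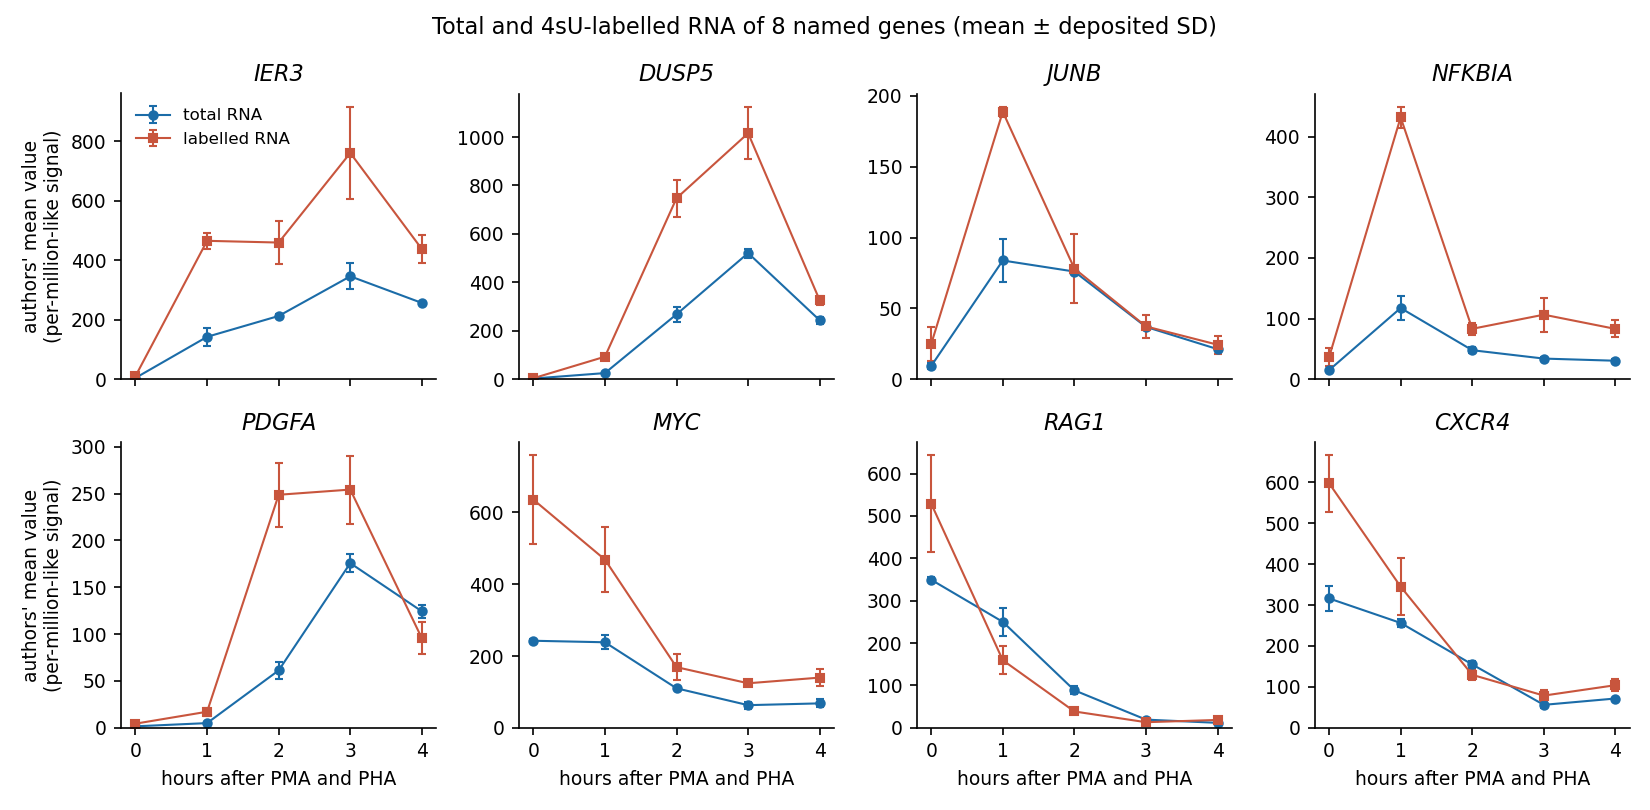
The authors' mean value (linear axis from 0 on a scale of its own in each panel, per-million-like units, error bars the deposited SD, n = 3, and n = 2 at 1 h) is plotted against hours after activation for IER3, DUSP5, JUNB, NFKBIA, PDGFA, MYC, RAG1 and CXCR4, with separate lines for total and labelled RNA. JUNB in total RNA peaks at 83.9 ± 15.0 at 1 h, DUSP5 at 521 ± 18.4 at 3 h, and RAG1 descends from 349 ± 5.96 to 11.8 ± 0.545 at 4 h.

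**Figure D2:**
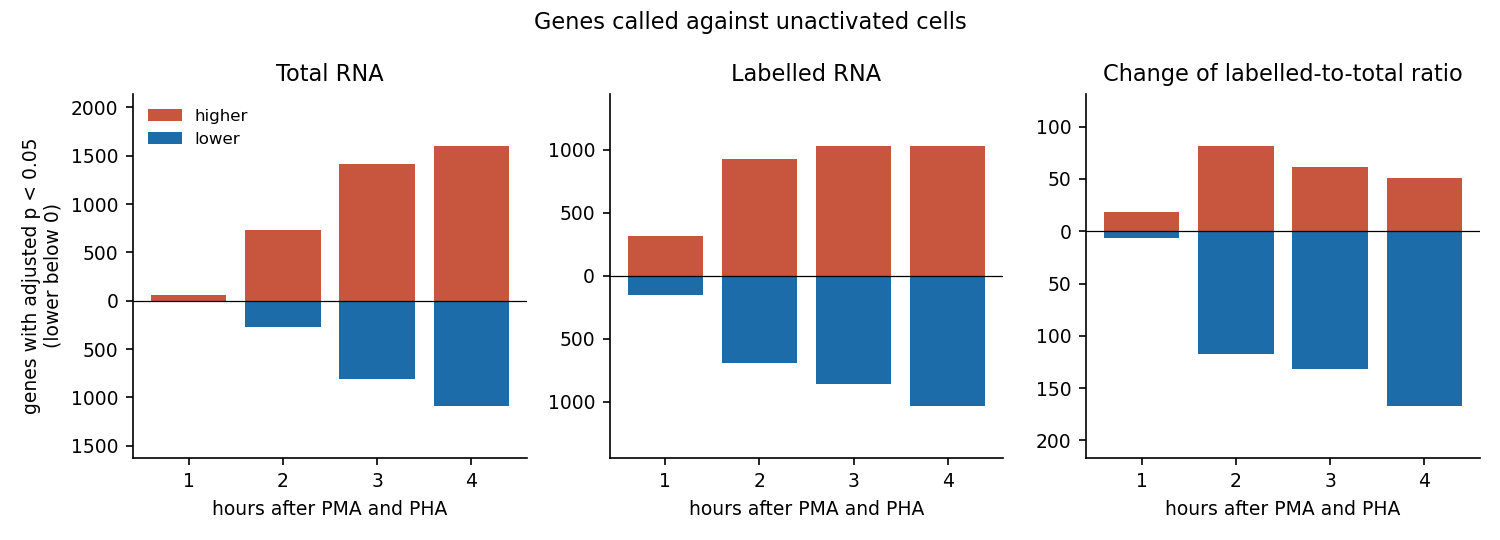
Bars give the number of genes called up (above 0) and down (below 0) by limma at each hour against unactivated cells, in panels for total RNA, labelled RNA and the change of their ratio. Calls in total RNA go from 59 up and 11 down at 1 h to 1605 up and 1087 down at 4 h, and calls of the ratio at 4 h are 51 up and 167 down.

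Labelled RNA was read next, as the newly made part relative to other genes, over a labelling time that is not given in the sources used here. At 1 h labelled IER3 rose by 5.33 ± 0.21, from 10.6 ± 4.23 to 466 ± 27.5, and labelled DUSP2 by 4.81 ± 0.14, from 71.1 ± 16.2 to 2022 ± 158. DUSP5 rose by 4.14 ± 0.16, KLF10 by 4.00 ± 0.16, CD83 by 3.55 ± 0.16, NFKBIA by 3.54 ± 0.23 and JUNB by 2.87 ± 0.29. Labelled RAG2 and RAG1 had already fallen by 2.16 ± 0.32 and 1.72 ± 0.22 at 1 h. So had SOX11 (-1.70 ± 0.24) and the POU factor POU3F2 (-1.64 ± 0.28). ACTB rose by 1.01 ± 0.19 (adjusted p = 0.0039 by limma), while MYC was at -0.44 ± 0.17 without a call (adjusted p = 0.108 by limma). DUSP5 lost its call on the linear scale (adjusted p = 0.335 by limma, range 7.09e-26 to 0.335).

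Heat shock genes in labelled RNA had 4 of 14 rise, 0 fall and 10 not called at 1 h (7 up adjusted over the list alone). They were led by HSPA8, the constitutive HSP70 chaperone, at 1.52 ± 0.11 (4561 ± 623 to 13104 ± 908) and its co-chaperone DNAJB1 at 1.66 ± 0.18. HSPA8 was the highest gene at both times, so quantile normalisation set its change to 0 by construction and ended its call without testing it (adjusted p = 1 by limma, range 5.73e-50 to 1). Histone genes had 17 of 35 fall, 0 rise and 18 not called (28 down adjusted over the list alone). Among them were HIST1H4D at -1.42 ± 0.24 (108 ± 15.4 to 39.6 ± 17.2), HIST1H4B at -1.34 ± 0.20 and HIST1H3C at -0.96 ± 0.19, although reads of such near-identical genes are hard to assign to 1 copy. Immediate early genes had 6 of 11 rise, 0 fall and 5 not called (7 up and 1 down adjusted over the list alone), and MAP kinase feedback 4 of 7 rise, 0 fall and 3 not called (4 up adjusted over the list alone). NF-kB targets had 8 of 17 rise, 0 fall and 9 not called (10 up adjusted over the list alone), with TNFAIP3 at 3.37 ± 0.20. T cell identity transcription factors had 2 of 18 rise, 5 fall and 11 not called (3 up and 7 down adjusted over the list alone). The progenitor factors MYB and TCF7 stood at -0.95 ± 0.12 and -0.84 ± 0.18 and, upward, ID3 at 1.31 ± 0.29. Cholesterol genes had 5 of 18 rise, 0 fall and 13 not called (6 up adjusted over the list alone). INSIG1, the sterol-regulated brake on SREBP, stood at 1.41 ± 0.14 and the LDL receptor at 0.80 ± 0.18. Ribosome biogenesis had 6 of 67 rise, 0 fall and 61 not called (8 up adjusted over the list alone), with the helicase DDX21 at 0.70 ± 0.10. The list tests in limma gave adjusted p of 4e-43 for immediate early genes, 8.2e-29 for NF-kB targets, 3.8e-19 for histones, 1.2e-08 for heat shock genes, 0.00016 for ribosome biogenesis, 0.0143 for cholesterol genes and 0.0221 for identity factors. The last 2 of these ended on ranks (adjusted p = 0.0988 each, ranges 0.0023 to 0.0988 and 0.00149 to 0.0988).

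By 4 h the labelled pool held many more falling groups. Ribosome biogenesis had 29 of 67 fall, 0 rise and 38 not called (39 down adjusted over the list alone). Nucleolin (NCL) stood at -0.78 ± 0.10, NOLC1 at -0.84 ± 0.11 (530 ± 8.72 to 295 ± 2.12), the box C/D protein NOP56 at -0.72 ± 0.11 and dyskerin (DKC1) at -0.76 ± 0.12. Cytosolic ribosomal proteins had 30 of 73 fall, 0 rise and 43 not called (36 down adjusted over the list alone). RPL12 fell by 0.72 ± 0.13, and the many pseudogenes of such genes make read assignment uncertain. Cholesterol genes had 8 of 18 fall, 1 rise and 9 not called (9 down and 1 up adjusted over the list alone). Among them were DHCR7 at -1.99 ± 0.28, INSIG1 at -1.57 ± 0.13 and the LDL receptor at -1.53 ± 0.16, against STARD4 at 0.97 ± 0.15. Glycolysis had 9 of 18 fall, 3 rise and 6 not called (10 down and 3 up adjusted over the list alone). SLC2A1 stood at -2.37 ± 0.23 and hexokinase 2 (HK2) at -2.23 ± 0.17, against SLC2A3 at 2.37 ± 0.22. The T cell receptor list had 14 of 26 rise, 1 fall and 11 not called (14 up and 2 down adjusted over the list alone). LCP2 rose by 2.14 ± 0.15, TRAT1 by 1.77 ± 0.13 and the phosphatase CD45 (PTPRC) by 0.69 ± 0.09. NF-kB targets had 9 of 17 rise, 0 fall and 8 not called (9 up adjusted over the list alone).

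Among single genes at 4 h, labelled DUSP5 (5.93 ± 0.14), IER3 (5.25 ± 0.19), PDGFA (4.15 ± 0.22), the tetraspanin CD82 (3.41 ± 0.23) and TMC6 (3.10 ± 0.23) rose furthest. RAG1 (-4.76 ± 0.20), RAG2 (-3.34 ± 0.28), SELPLG (-2.91 ± 0.25), the thyrotropin receptor TSHR (-2.79 ± 0.28) and SMAD6, an inhibitor of BMP signalling (-2.68 ± 0.27), fell furthest. Labelled JUNB was back at -0.03 ± 0.26 from unactivated cells (adjusted p = 0.955 by limma), NFKBIA stayed at 1.17 ± 0.21 and MYC fell by 2.18 ± 0.15. The list tests in limma gave adjusted p of 1.2e-08 for ribosome biogenesis, 1.5e-06 for cytosolic ribosomal proteins, 2.9e-06 for the T cell receptor list, 3e-12 for NF-kB targets, 0.00029 for cholesterol and 0.0080 for glycolysis genes. Counted over all genes, limma called 468 in labelled RNA at 1 h (314 up, 154 down), 1617 at 2 h (924 up, 693 down), 1889 at 3 h (1034 up, 855 down) and 2060 at 4 h (1029 up, 1031 down). With only the groups compared there were 228 calls at 1 h, and 291 with a constant prior variance. Over the course 2960 changed in an F test. At 1 h the percent up among called genes was 67.1, with 71.6 under median centring and 56.8 under quantile normalisation. Between 1 h and 4 h 1697 genes changed (703 up, 994 down; 656 and 1032 with median centring, 801 and 814 with quantile normalisation). Over this interval 48 of 67 ribosome biogenesis genes fell, 0 rose and 19 were not called (52 down adjusted over the list alone; adjusted p = 2.4e-20 in limma). Of 14 heat shock genes 7 fell, 0 rose and 7 were not called (8 down adjusted over the list alone; adjusted p = 3.0e-08 in limma). Of 35 histone genes 11 rose, 0 fell and 24 were not called (13 up adjusted over the list alone; adjusted p = 7.2e-06 in limma).

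Setting labelled against total RNA within unactivated cells showed which transcripts had more or less labelled RNA than the typical gene, a comparison that bears on the study's question of mRNA stability. The highest ratios were those of the zinc finger gene ZNF827 (log2 ratio 2.89 ± 0.26, from 1.70 ± 0.351 in total to 19 ± 4.84 in labelled RNA), the secreted hormone STC2 (2.84 ± 0.23) and C20orf112 (2.73 ± 0.21). Next came the AP-1 subunit FOSL2 (2.67 ± 0.25), the prostaglandin receptor PTGER4 (2.58 ± 0.16), the oxygen sensor EGLN2 (2.57 ± 0.18), TRAPPC9 (2.54 ± 0.19) and ZNF780B (2.52 ± 0.16). The lowest were TMEM14C, a mitochondrial carrier needed for haem synthesis (-2.26 ± 0.23, from 25.9 ± 1.43 to 4.61 ± 1.73), and its relative TMEM14A (-2.16 ± 0.23). HRSP12 (-2.06 ± 0.21) followed, with the ribosomal protein pseudogene RPSAP58 (-2.0 ± 0.28, uncertain because its parent gene is near-identical). Then came the pyrophosphatase PPA2 (-1.96 ± 0.19), RPL27 (-1.92 ± 0.22), the sorting nexin SNX3 (-1.88 ± 0.15) and the spliceosomal SNRPF (-1.87 ± 0.15). JUNB (1.32 ± 0.23), MYC (1.39 ± 0.15) and NFKBIA (1.22 ± 0.19) were higher in labelled RNA, and GAPDH (-1.30 ± 0.18), ACTB (-1.01 ± 0.15) and ELAVL1 (-0.69 ± 0.13) lower. On the linear scale JUNB and NFKBIA lost their calls (adjusted p = 0.0809 and 0.089 by limma, ranges from 5.49e-06 and 1.08e-06 to those values).

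Whole classes stood apart in unactivated cells. KRAB zinc finger genes were higher in labelled RNA for 93 of 100, lower for 0 and not called for 7 (94 up adjusted over the list alone). Their median was 1.15 against 0.15 for all genes, with ZNF420 at 2.17 ± 0.16 and ZNF267 at 1.99 ± 0.14. Immediate early genes were higher for 10 of 11, lower for 0 and not called for 1 (10 up adjusted over the list alone). T cell identity factors were higher for 14 of 18, lower for 0 and not called for 4 (14 up adjusted over the list alone), with the chromatin organiser SATB1 at 1.27 ± 0.09. MAP kinase feedback genes were higher for 7 of 7 (7 up adjusted over the list alone). Genes of the respiratory chain were lower for 47 of 58, higher for 1 and not called for 10 (47 down and 2 up adjusted over the list alone). The ATP synthase subunit ATP5C1 stood at -1.59 ± 0.12 and COX7B at -1.69 ± 0.14. Proteasome subunits were lower for 24 of 31, higher for 3 and not called for 4 (24 and 3 adjusted over the list alone), with PSMD13 at -1.47 ± 0.13. Mitochondrial ribosomal proteins were lower for 36 of 58, higher for 4 and not called for 18 (36 and 4), and histones lower for 27 of 35, higher for 1 and not called for 7 (27 and 2). Cytosolic ribosomal proteins went both ways, lower for 45 of 73, higher for 15 and not called for 13 (45 and 16 adjusted over the list alone). RPS20 stood at -1.70 ± 0.14 and RPL5 at -1.33 ± 0.11 but RPS10 at 2.18 ± 0.20 (4.66 ± 0.765 in total, 24.7 ± 3.22 in labelled RNA) and RPL41 at 1.85 ± 0.14, whose assignment among pseudogenes is uncertain. After a trend of the ratio with uridine number was removed, the median distance from all genes went from -1.02 to 0.0478 for histones, from -0.990 to -0.568 for the respiratory chain and from -0.784 to -0.343 for cytosolic ribosomal proteins, and it stayed at 0.969 for KRAB genes (1.00 before).

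The list tests of the unactivated ratio in limma gave adjusted p of 3.7e-16 for KRAB genes, 2.3e-11 for the respiratory chain, 1.3e-07 for the proteasome, and 3.9e-07 for mitochondrial ribosomal proteins. In limma they gave adjusted p of 6.1e-06 for histones, 1e-05 for cytosolic ribosomal proteins, 5.9e-05 for immediate early genes, 0.0016 for identity factors and 0.0050 for MAP kinase feedback. Spliceosome genes (adjusted p = 5.9e-05), ribosome biogenesis (0.0011), glycolysis (0.0014), G2 and M genes (0.0021) and S phase genes (0.0050) also lay low in the same limma tests. Glycolysis had PGK1 at -1.48 ± 0.12 and ENO1 at -1.60 ± 0.13. Counted over 7485 genes, limma called 3041 higher and 2015 lower in labelled RNA before activation. These numbers were 2584 and 1925, 2777 and 2262, 2844 and 2137, and 2953 and 2248 at 1, 2, 3 and 4 h. The median of all genes was 0.15 before activation and -0.04 with median centring, a shift of 0.198, which took the percent of called genes that were higher from 60.2 to 46.3. NF-kB targets, higher for 11 of 17 and lower for 3 (the same adjusted over the list alone; adjusted p = 0.0464 in limma), lost their call in 4 of 7 alternatives. These were ranks (adjusted p = 0.0857), a pseudocount of 5 (0.0673), rebuilt values (0.058) and quantile normalisation (0.0576) in limma, out of a range of 0.0394 to 0.0857.

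**Figure D3:**
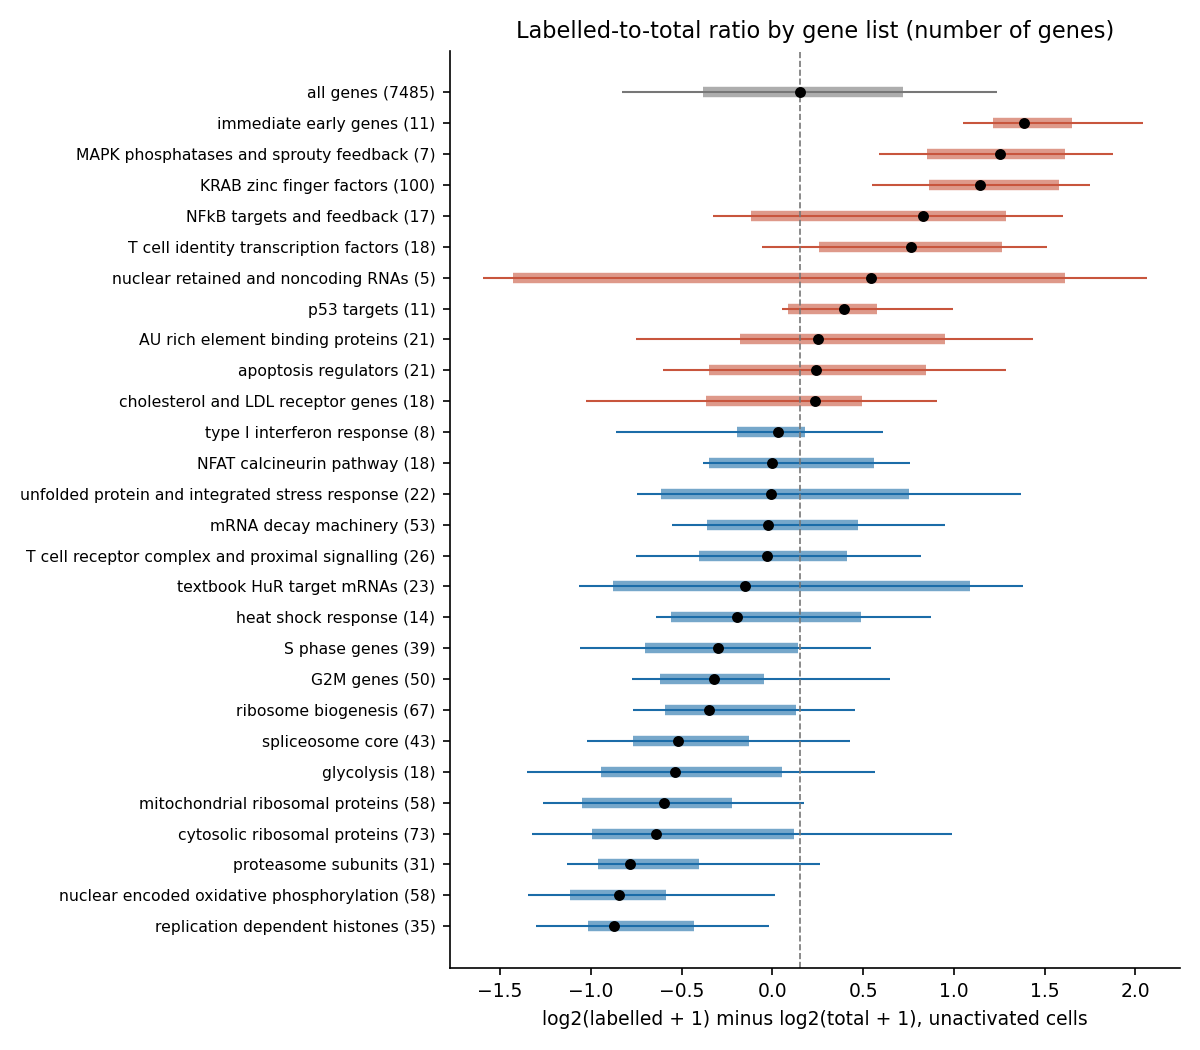
The log2 ratio of labelled to total RNA in unactivated cells (horizontal axis, n = 3 samples each) is drawn per gene list, with the median gene as a dot, the quartiles as a thick bar, the 10th to 90th percentile as a thin line and the median of all genes, 0.15, as a dashed line. KRAB zinc finger genes lie highest of the large lists with a median of 1.15, and respiratory chain genes (-0.85) and histones (-0.87) lie lowest.

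Whether labelled and total RNA responded differently was tested as the change of the ratio from unactivated cells. At 1 h the ratio rose for CD83 by 1.47 ± 0.20 (adjusted p = 8.7e-05 by limma). Its total value went from 25 ± 2.45 to 109 ± 20.3 and the labelled value from 32.5 ± 5.43 to 392 ± 45.4. It also rose for N4BP3 (1.85 ± 0.34), CD82 (1.59 ± 0.27), RBM38, an RNA-binding p53 target (1.55 ± 0.28), DUSP5 (1.44 ± 0.22), HSPA8 (1.11 ± 0.19) and NFKB1 (1.09 ± 0.16). The ratio fell for RAG2 (-1.78 ± 0.38), HIST2H2BF (-1.51 ± 0.35), RAG1 (-1.24 ± 0.26) and MYB (-0.93 ± 0.14). The labelled value of MYB went from 795 ± 35.9 to 411 ± 63.3 while its total value was 753 ± 25.6 and 743 ± 12.5. When only the groups compared were used, the calls of N4BP3, CD82, RBM38, DUSP5 and HIST2H2BF ended, with adjusted p of 0.134, 0.0726, 0.0944, 0.192 and 0.168 in limma. Over their alternatives the adjusted p ran from 0.000732 to 0.134, 0.000276 to 0.476, 0.000502 to 0.0944, 1.13e-05 to 0.708 and 0.0446 to 0.459. HIST2H2BF lost its call in 7 alternatives, median centring (adjusted p = 0.0513 in limma) among them. On the linear scale N4BP3, CD82 and DUSP5 also lost theirs (adjusted p = 0.0541, 0.476 and 0.708 in limma). HSPA8, the highest gene in both kinds of RNA at both times, was again set to 0 by quantile normalisation (adjusted p = 1 in limma, range 0.000333 to 1).

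At 4 h 167 of 218 called ratios had fallen, and on the linear scale, where a difference and not a ratio is tested, 173 of 350. CD55, which shields cells from complement, fell by 2.36 ± 0.33 in the ratio, with labelled values of 19.3 ± 7.87 and 3.94 ± 1.45 and total values of 17.1 ± 2.67 and 21.6 ± 3.41. HK2 fell by 1.75 ± 0.18, FOSL2 by 1.67 ± 0.35, ERO1LB, an oxidase of protein folding, by 1.58 ± 0.29, and INSIG1 by 1.58 ± 0.16. The labelled value of INSIG1 went from 405 ± 98.7 to 136 ± 14.5 while the total was 333 ± 12.5 and 336 ± 22.6. SRF, the serum response factor, fell by 1.51 ± 0.19, KLF10 by 1.47 ± 0.26, VEGFA by 1.31 ± 0.34 and DUSP2 by 1.03 ± 0.18. The ratio rose for TCTA (1.83 ± 0.36), UBL7 (1.38 ± 0.33), ZFYVE19 (1.37 ± 0.32), PLGRKT (1.29 ± 0.32), MICAL2 (1.22 ± 0.33), the adaptor PAG1 (0.94 ± 0.27) and THEMIS, a regulator of T cell receptor signalling (0.74 ± 0.16). When only the groups compared were used, the calls of UBL7, MICAL2, PAG1 and VEGFA ended, with adjusted p of 0.0652, 0.0892, 0.0846 and 0.08 in limma. A constant prior variance ended that of PAG1 (adjusted p = 0.0735 in limma), and the linear scale those of UBL7, FOSL2 and VEGFA (0.174, 0.124 and 0.235) and turned KLF10 and DUSP2 upward without a call (0.931 and 0.658). Over their alternatives the adjusted p ran from 0.0112 to 0.174 for UBL7, 0.000814 to 0.0892 for MICAL2, 0.00865 to 0.0846 for PAG1, 0.0185 to 0.235 for VEGFA, 0.00419 to 0.124 for FOSL2, 0.00115 to 0.931 for KLF10 and 0.000828 to 0.658 for DUSP2. JUNB stood at -1.13 ± 0.33 (adjusted p = 0.0505 by limma) and was not called at 4 h.

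The ratio of ribosome biogenesis genes fell at 4 h for 12 of 67, rose for 0 and was not called for 55 (20 down adjusted over the list alone). NOLC1 stood at -0.75 ± 0.13, UTP14A at -0.92 ± 0.17 and DDX21 at -0.84 ± 0.12. NOLC1 lost its call on the linear scale (adjusted p = 0.277 in limma, range 0.00115 to 0.277). Immediate early genes had 5 of 11 fall, 0 rise and 6 not called (7 down adjusted over the list alone). Glycolysis had 3 of 18 fall, 0 rise and 15 not called (4 down and 1 up adjusted over the list alone), and cholesterol genes 1 of 18 fall, 0 rise and 17 not called (1 down adjusted over the list alone). Cytosolic ribosomal proteins had a median of -0.21 with 0 of 73 called by limma over all genes and 0 adjusted over the list alone. There were 0 up and 12 down at an unadjusted p under 0.05. G2 and M genes had a median of 0.16, with 1 of 50 falling, 0 rising and 49 not called (0 called adjusted over the list alone). The list tests in limma gave adjusted p of 1.5e-10 for ribosome biogenesis, 6.3e-10 for immediate early genes, 1.8e-05 for glycolysis, 0.00021 for cholesterol genes, 0.0046 for cytosolic ribosomal proteins and, upward, 0.00054 for G2 and M genes. Textbook HuR targets had 2 of 23 fall, 0 rise and 21 not called (4 down adjusted over the list alone; adjusted p = 0.0205 in limma). This call ended in limma with the stricter filter (adjusted p = 0.114) and with quantile normalisation (adjusted p = 0.0608, range 0.0184 to 0.114). At 1 h the ratio of NF-kB targets had 2 of 17 rise, 0 fall and 15 not called (2 up adjusted over the list alone; adjusted p = 1.1e-06 in limma). The ratio of histones had a median of -0.39 with 0 of 35 called by limma over all genes, 2 down adjusted over the list alone, and 0 up and 9 down at an unadjusted p under 0.05 (adjusted p = 3.6e-05 in limma). Limma called 24 ratios changed at 1 h (18 up, 6 down), 199 at 2 h (82 up, 117 down), 193 at 3 h (61 up, 132 down) and 218 at 4 h (51 up, 167 down). With only the groups compared there were 11, 138, 57 and 71 calls at these hours (8, 56, 17 and 21 up), and on the linear scale 101, 416, 438 and 350 (47, 154, 199 and 177 up). The percent up was 75, 41.2, 31.6 and 23.4 among the 24, 199, 193 and 218 calls and 46.5, 37.0, 45.4 and 50.6 among those on the linear scale, against 91.8, 68.6, 52.1 and 34.9 with median centring and 84.6, 55.0, 45.2 and 40.3 with quantile normalisation.

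The study's own measure of stability was a decay rate per hour, more negative for faster loss, taken from the authors' deposited table. JUNB had a deposited rate of -1.22 before activation and 1.27 at 1 h, and MYC -1.19, -0.758, -1.30, -1.30 and -0.715 before activation and at 1, 2, 3 and 4 h in the authors' deposited table. The median gene had rates of -0.344, -0.291, -0.326, -0.359 and -0.359 at these times in the authors' deposited table. Rates above 0, which loss alone cannot give, were held by 181 (2.46%), 137 (1.86%), 122 (1.65%) and 71 (0.963%) genes at 1, 2, 3 and 4 h. Before activation no rate could lie above 0, because the same total value stood above and below the line. Tested with limma on the deposited rates and SDs, 0 of 7176 genes were called at any hour. An unadjusted p under 0.05 was found for 239, 312, 531 and 338 genes at 1, 2, 3 and 4 h. The lack of calls does not show that rates held steady. The SDs of the rates are carried over from those of group means, and rates of neighbouring hours share a mean of total RNA. No simulation was run on rates, so what this test could find is unknown. The T scores of the authors' deposited table gave 0 calls at each hour after adjustment, with 221, 437, 386 and 246 genes at an unadjusted p under 0.05. A constant prior variance gave 0, 1, 3 and 0 calls in limma, and only the groups compared gave 98, 30, 0 and 20. The rate was less negative than before activation for 68.7%, 57.3%, 46.0% and 47.9% of genes at 1, 2, 3 and 4 h. These shares move with scaling, since a rate after activation divides by total RNA of the hour before. The total RNA means summed to 958269 before activation and to 1017442, 1037463, 1027995 and 1008859 at 1, 2, 3 and 4 h. Whether loss slowed across genes cannot be told from these shares.

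HuR, encoded by ELAVL1, binds AU- and U-rich elements and stabilises many mRNAs, and the study asked about its part in activation. MYC, an mRNA that HuR binds, had HuR scores of 0.250 at 0 h and 1.12 at 4 h in the authors' deposited table, and ELAVL1 itself 1.33 and 0.876. The authors' HuR_Any call, made among genes that have these scores, named 584 targets. How it relates to the other calls is not given in the sources used here. Of these targets, 34.1% rose and 8.90% fell in total RNA at 4 h, against 19% and 14.9% of 4433 other genes. The median difference was 0.12 (adjusted p = 0.0015 in limma). At 3 h 29.1% rose against 17.6% of other genes (adjusted p = 0.0098 in limma), and at 1 h 1.20% against 0.947% (adjusted p = 0.488 in limma). Between 1 h and 4 h 20.5% of these targets rose, against 10.4% (adjusted p = 0.0015 in limma). Genes called targets in the 3' UTR, 4345 against 2779, rose for 26.3% against 14.4% at 4 h (median difference 0.11, adjusted p = 0.0458 in limma). This difference lost its call in limma with quantile normalisation (adjusted p = 0.103) and with median centring (adjusted p = 0.0652, range 0.00279 to 0.103). The iCLIP targets, 1455 against 6030, rose for 28.9% against 19.7% (adjusted p = 0.101 in limma). Genes with a positive score in a kidney-derived line, 962 against 5414, rose for 26.9% against 20.7% (adjusted p = 0.347 in limma). The calls in the authors' deposited table were chosen by the study, in samples that are not given in the sources used here, so they are not independent evidence of a direction.

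In labelled RNA the targets of the authors' 3 calls were higher at 1 h. The HuR_Any targets rose for 10.4% against 4.13% of other genes, iCLIP targets for 7.08% against 3.50% (adjusted p = 0.0363 each in limma). The 3' UTR targets rose for 4.97% against 3.13% (adjusted p = 0.0397 in limma). All of these ended with quantile normalisation (adjusted p = 0.371 each, ranges from 0.00967, 0.00967 and 0.0123 to 0.371). At 4 h the HuR_Any targets rose for 21.2% against 11.9% in labelled RNA, with an adjusted p of 0.205 in limma. The labelled-to-total ratio of HuR targets passed no test against other genes in unactivated cells (adjusted p between 0.316 and 0.828 in limma over the 3 calls and the positive score). Its change at 1 h was higher for iCLIP and HuR_Any targets by 0.08 and 0.07 (adjusted p = 0.0481 each in limma). Both calls ended in limma with quantile normalisation (adjusted p = 0.233) and with the stricter filter (adjusted p = 0.0571, range 0.0142 to 0.233). At 4 h the ratio fell for 4.79% of HuR_Any targets against 2.03% of other genes (adjusted p = 0.101 in limma).

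**Figure D4:**
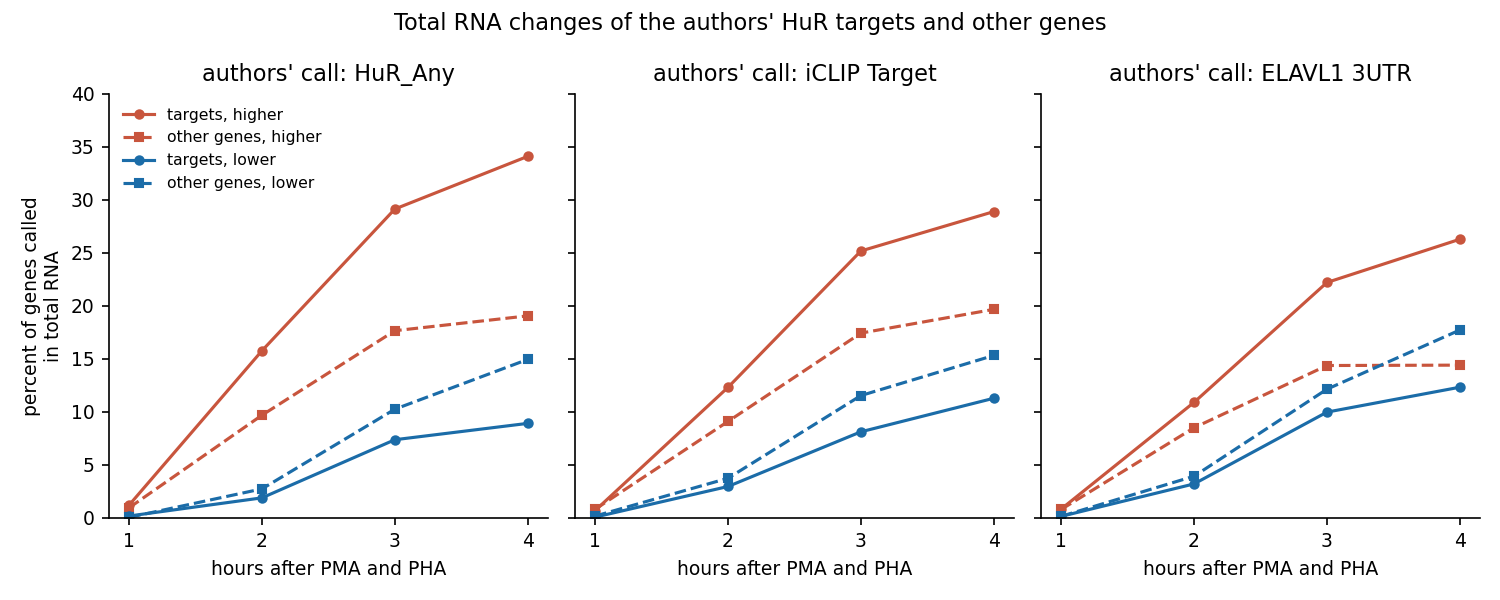
The percent of genes called higher (red) and lower (blue) in total RNA by limma is plotted against hours after activation for HuR targets (solid lines) and other genes (dashed lines), in 1 panel for each of 3 calls of the authors. At 4 h 34.1% of the HuR_Any targets are higher, against 19% of other genes, and 8.90% are lower, against 14.9%.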

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

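The tests of scaling and of an early labelled rise were chosen only after the result was seen. All results given here were singled out because the activation response differed between labelled and total RNA in an interaction test, by limma at an adjusted p under 0.05, with n = 3 a group and n = 2 at 1 h. The labelled-to-total ratio had changed from unactivated cells for 24 genes at 1 h, 199 at 2 h, 193 at 3 h and 218 at 4 h.

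Among the genes named whatever their values, JUNB had a ratio change of -1.28 ± 0.33 at 2 h (adjusted p = 0.0243 by limma) and of -1.30 ± 0.33 at 3 h (adjusted p = 0.0220 by limma). Both changes are from unactivated cells, where labelled JUNB already stood above total JUNB. Its ratio was not called changed at 1 h. At 1 h the labelled value of JUNB was 189 ± 3.65 and the total value 83.9 ± 15.0, and by 2 h they were 78.2 ± 24.1 and 76.0 ± 1.87. MYC had a ratio change of -0.77 ± 0.21 at 2 h (adjusted p = 0.0326 by limma), with total RNA at 110 ± 3.78 and labelled RNA at 169 ± 36.3. Over 10 alternatives the adjusted p ran from 0.02 to 0.577 for JUNB at 2 h, from 0.0182 to 0.503 at 3 h and from 6.18e-05 to 0.0718 for MYC at 2 h, with 3 calls ended in each.

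The pattern of most interest is that, without rescaling, called ratios fell more often than they rose. Falls were 117 of 199 calls at 2 h, 132 of 193 at 3 h and 167 of 218 at 4 h. With only the groups compared they were 82 of 138, 40 of 57 and 50 of 71. On the linear scale, where a difference and not a ratio is tested, they were 262 of 416, 239 of 438 and at 4 h only 173 of 350. How the 2 kinds of library were put on 1 scale is not known here, and the percent of rises among called genes moved with the scaling, from 41.2 to 68.6 at 2 h (226 genes called; 95% interval 62.5 to 74.6) and from 31.6 to 52.1 at 3 h with every group centred on its median, and to 55.0 and 45.2 with quantile normalisation. At 4 h it went from 23.4 to 34.9 with centring (169 genes called; 95% interval 27.7 to 42.1) and to 40.3 with quantile normalisation, around the bound of 40 set for scaling as the cause. Both scalings turned the 2 h balance to more rises than falls, so the direction at 2 h depended on the scaling. At 3 h centring alone turned it, and at 4 h falls stayed more frequent under both. Centring shifts every gene alike and so moves this balance by construction, and the 2 h value lay past that bound before it. Which scaling is right is not known, so whether scaling caused the falls stays open at each hour. An early burst of labelled RNA that had ended by 4 h, the biological explanation tried, also stays open, since 13.8% of the 167 genes with a fallen ratio (23 genes) had a called labelled rise at 1 h against 3.98% of other genes, a difference of 9.80 percentage points (95% interval 4.55 to 15.0) that lay above 0 and under the 20 points set for it, in a comparison where the simulation recovered 12% of genes changed by 0.5. The 95% intervals in this section are binomial over genes, which share the same samples and are not independent. They hold no spread between cultures.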

How the results depend on the processing

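Linear scale, rebuilt values, constant prior variance and ranks, and every test of HuR lists and decay rates, were chosen only after the data had been seen. So were quantile normalisation, the stricter filter and the pseudocounts where they were applied to gene lists. Of 206 counts of called genes under alternatives, 175 stayed within 1.5 times the main count and 31 did not. Of 1351 gene list results 1289 kept direction and side of the threshold and 62 ended, 35 of them on ranks and 11 with quantile normalisation, and none turned the direction of its test in these 7 alternatives. The median of 2 lists did change sign: p53 targets in total RNA at 1 h went from 0.06 to -0.02 with median centring and -0.01 with quantile normalisation, and T cell identity factors in labelled RNA at 3 h from 0.04 to -0.07 with quantile normalisation, where the test of the identity factors went downward in both. Beside the p53 targets the median of other genes went from 0.07 to -0.02 and -0.005, so that sign change came with the shift of all genes. Beside the identity factors it went from 0.004 to -0.02. Of 9085 results for named genes, 8510 kept both, 481 lost the call, 90 gained one and 4 reversed. No paired analysis was possible because the columns hold group means and SDs and carry no replicate letters. For the same reason leaving out each sample, count-based tools, camera with an estimated correlation and fry were not run, nor could samples be split otherwise. Without a filter the results were identical, since the low-value filter removed no gene. What depth limits could not be tested without counts. With the deposited SDs pooled over the hours and the same n, the simulation found 58% of genes changed by 1 in labelled RNA and 60% for the ratio change at 1 h.

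With median centring 49 ratios changed at 1 h. With only the groups compared, total RNA had 161 calls at 1 h and 1703 at 2 h, labelled RNA 228 at 1 h, and the ratio change 11 at 1 h, 57 at 3 h and 71 at 4 h. Decay rates had 98 at 1 h, 30 at 2 h and 20 at 4 h. Fewer samples then set the spread, and only those of the groups compared. Calls against unactivated cells fell in labelled RNA and in the ratio at every hour, and in total RNA at 3 h (2229 to 1495). They rose in total RNA at 1, 2 and 4 h (2692 to 3132 at 4 h). The median coefficient of variation was highest in labelled RNA of unactivated cells (18.2%) and, within total RNA, at 3 h (11.2%). Whether this uneven spread moved the counts was not tested. A log2 change of at least 1, a demand that by construction can only lower counts, left 25, 86, 240 and 270 genes in total RNA at 1, 2, 3 and 4 h and 204 between 1 h and 4 h. It left 133, 346, 471 and 430 in labelled RNA and 365 between 1 h and 4 h. For labelled against total RNA it left 1615 before activation and 1592, 1525, 1539 and 1718 at 1, 2, 3 and 4 h, and for the ratio change 80, 70 and 54 at 2, 3 and 4 h. On the linear scale total RNA had 41 calls at 1 h and the ratio change 101, 416, 438 and 350 at 1, 2, 3 and 4 h, where the test is of a difference and not of a ratio. A constant prior variance gave 291 calls in labelled RNA at 1 h and, for decay rates, 1 at 2 h and 3 at 3 h; the cause was not tested.

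For HuR lists, the median difference of 3' UTR targets in total RNA at 4 h was 0.105 with quantile normalisation and 0.110 with median centring, without a call (adjusted p = 0.103 and 0.0652 in limma; range over 7 alternatives 0.00279 to 0.103). With quantile normalisation labelled RNA at 1 h gave 0.0304 for iCLIP, 0.0308 for 3' UTR and 0.0381 for HuR_Any targets (adjusted p = 0.371 each in limma, the highest over 7 alternatives). The ratio change at 1 h gave 0.0405 for iCLIP and 0.0453 for HuR_Any targets with quantile normalisation (adjusted p = 0.233 each in limma). With the stricter filter it gave 0.0775 and 0.0673 (adjusted p = 0.0571 each in limma), out of ranges of 0.0142 to 0.233. The cause was not tested. Results that reversed were all ratio changes on the linear scale, in units of the deposited means: JUNB at 1 h at 89.5 (adjusted p = 5.02e-05 in limma, range 5.02e-05 to 0.981), and at 4 h KLF10 at 11.6 (adjusted p = 0.931), DUSP2 at 108 (0.658) and MCL1 at 52.0 (0.816). A difference of values grows with the level of the gene, which a ratio leaves out.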

Other observations

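No test reported here was chosen only after the result was seen, except the HuR lists and decay rates, which were not among the comparisons fixed beforehand. Between the early and late hours, groups of genes moved that the comparisons above describe only at 1 h and 4 h. In total RNA at 3 h AU-rich element binding proteins had 10 of 21 rise, 0 fall and 11 not called (12 up adjusted over the list alone; adjusted p = 0.0087 in limma). CELF2 went from 105 ± 8.26 before activation to 120 ± 7.44, 191 ± 45.4 and 254 ± 11.5 at 2, 3 and 4 h. RC3H1, which encodes Roquin, an mRNA decay factor that restrains T cells, went from 86.8 ± 2.93 to 111 ± 8.64, 167 ± 32.1 and 148 ± 14.4. KRAB zinc finger genes had 35 of 100 fall, 6 rise and 59 not called at 3 h (39 down and 8 up adjusted over the list alone; adjusted p = 4.6e-05 in limma), with ZNF480 at 33.8 ± 1.66 before activation and 16.5 ± 2.88 at 3 h. G2 and M genes had 17 of 50 fall, 1 rise and 32 not called (18 down and 2 up adjusted over the list alone; adjusted p = 0.00998 in limma), with TTK at 242 ± 18.4 before activation and 164 ± 4.77 at 3 h.

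INSIG1 and HK2, singled out after their values were seen, had labelled values that peaked at an earlier hour than their total values, a difference that was not tested. Labelled INSIG1 stood at 405 ± 98.7, 1080 ± 216, 620 ± 23.1, 292 ± 1.33 and 136 ± 14.5 before activation and at 1, 2, 3 and 4 h. Total INSIG1 was 333 ± 12.5, 536 ± 11.7, 907 ± 19.4, 726 ± 59.1 and 336 ± 22.6. Labelled HK2 went from 151 ± 6.53 to 178 ± 20.4, 107 ± 18.3, 41.2 ± 2.92 and 31.5 ± 2.92. Total HK2 was 130 ± 2.63, 145 ± 7.41, 174 ± 5.58, 173 ± 26.4 and 93.1 ± 9.33. MYB, a factor of immature T cells, went down and back, with labelled values of 795 ± 35.9, 411 ± 63.3, 395 ± 13.4, 656 ± 18.3 and 908 ± 102. Among histones, 17, 15, 6 and 5 of 35 genes had fallen in labelled RNA at 1, 2, 3 and 4 h and 0 had risen (28, 19, 4 and 2 down adjusted over the list alone; adjusted p = 3.8e-19, 1.1e-06, 0.0395 and 0.0646 in limma). HIST1H4B, a near-identical copy, was at 171 ± 34.8, 67.1 ± 7.97, 82.8 ± 14.3, 102 ± 4.94 and 131 ± 39.6.

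The labelled-to-total ratio of gene classes in unactivated cells could follow the number of uridines in a transcript, since each is a place where the label can enter. A trend with uridine number took up 12.5% of the variance of the ratio over 7401 genes. Intervals are 95% from 10000 bootstrap draws of the genes of a list. KRAB zinc finger genes stayed at 0.969 above all genes after its removal (0.805 to 1.10; 1.00 before; 100 genes), which argues against uridine number as their whole cause. Histones went from -1.02 to 0.0478 (-0.123 to 0.324, 35 genes). Their median transcript had 503 bases against 3793 for all genes, so uridine number cannot be told apart from other traits of such short transcripts. Whether short transcripts escaped the label thus stays open. The respiratory chain went from -0.990 to -0.568 (-0.728 to -0.399; 58 genes) and cytosolic ribosomal proteins from -0.784 to -0.343 (-0.519 to -0.111; 73 genes), intervals that span the line between both outcomes and leave it open. ATTTA motifs of the 3' UTR, a mark of unstable mRNAs and the biological explanation tried, correlated with the ratio at a Spearman's rho of 0.219 across genes. The rho was -0.0565 (p = 1e-05, the smallest that 100000 permutations can give; 7362 genes, which are not independent replicates) once uridine number and 3' UTR length were removed from both, against the rise predicted. Motifs hold uridines and lie in the 3' UTR, so removing both features may also take out part of a motif effect. For that reason this test cannot decide whether the motifs matter.

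The greater rise of HuR targets in total RNA at 4 h may rest on other features of these transcripts. The HuR_Any targets had a median 3' UTR of 2520 bases against 1237 and a median total value of 131 against 72.9. Their mean difference from other genes went from 0.158 to 0.0907 (95% interval 0.0453 to 0.136; 582 against 4412 genes) after trends with abundance, 3' UTR length and uridine share were removed. Part of it remained, and whether the features account for most of it is open. If HuR slowed the loss of the transcripts it gained, the gain of the authors' HuR score from 0 h to 4 h should go with a less negative decay rate. Spearman's rho across 4908 genes was -0.0326 (permutation p = 0.0214), opposite in sign and under the 0.05 set for it. In limma the rate change at 4 h had 0 of 7176 genes called and 338 at an unadjusted p under 0.05. Noise in the rates pulls a rho toward 0, so this test cannot decide the question. The gain of the score correlated with the change of total RNA at 4 h at a rho of 0.0312 across 5017 genes (permutation p = 0.0277), under the 0.05 set beforehand and too close to it to decide. Genes are not independent replicates.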
